A study of Mus musculus with 11 samples.

How the data were processed

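RNA-seq was performed on HC800-A8-1, a cell line derived from a mouse pancreatic ductal adenocarcinoma (PDAC), grown in 2D culture in serum-containing medium. Cells were transduced with a lentivirus carrying Cas9 and guide RNAs. Control libraries came from cells that received a non-targeting guide. Knockout libraries came from clones grown from single cells, each made with a guide against Six1 (guide A, in every clone) and a guide against Six4 (guide G or guide H, giving the pairs AG and AH). RNA was extracted with TRIzol and column purification, and libraries were made with a stranded poly(A) kit, per the labels' protocols.

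The authors deposited raw read counts per gene, in 2 tables. The tables, called run 1 and run 2 here, match the 2 number series in the sample titles. Reads were aligned with STAR 2.5.4a and counted with featureCounts 1.6.3, per the submitters' processing notes, which also name DESeq2 1.26.0. Those notes name the genome build GRCh38, a human build, whereas every feature in the deposited count tables carries a mouse Ensembl identifier. The annotation release, the strand setting of the counting and the treatment of multi-mapped reads are not given in the sources used here. The deposited counts are whole numbers whose totals differ between libraries, and the tables hold no unassigned-read rows. Both tables list the same 53801 identifiers. Symbols were taken from a reference table that held 53620 of them (99.7%), and the unmatched identifiers took 0.0428% of the counts. Coordinates are from the GENCODE annotation of the mouse build GRCm38, matched by gene identifier, since the count tables hold none.

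Groups, clone names and runs were taken from the sample titles. The descriptions of the 3 knockout libraries of run 2 name other clones than their titles and source names do, and the titles were used. Run 1 held 2 control libraries and 1 library of each of 5 clones (AG#15, AH#3, AG#12, AH#24, AG#2). Run 2 held control replicate 3 and further libraries of AH#24, AG#15 and AG#2. Nothing in the labels says that the control libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical for the controls. No library came from a single-cell clone of control cells, so knockout and cloning were not separated by the design. Library pairs were compared by chi-square of their counts over genes. The statistic per degree of freedom was 16.1 or more for every pair, so no pair agreed within sampling noise and all libraries were kept.

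The main comparison used run 1 only, so that each clone entered with 1 library. Counts were filtered with filterByExpr, scaled by the trimmed mean of M values (TMM) and tested with the edgeR 4.0.16 quasi-likelihood test (robust, two-sided) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Every adjusted p in the text is from this test unless another tool is named. Fold changes are knockout over control with a prior count of 0.125, and their standard errors (SE) were derived from the quasi-likelihood F statistic. Levels are CPM (counts scaled to a common library size) computed here with the TMM factors of each run, while principal components used log2 CPM scaled over all 11 libraries. For a gene with 0 counts in all clones of run 1, the fold is given as a bound against a floor of 3 counts over the 5 clones together (0.0298 CPM). This bound covers counting error only. Fitted fold changes of genes with a few counts depend on the prior count, and levels are given for these genes instead.

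Run 2 was tested alone as a repeat (1 control, 3 clones), where the lone control was assumed to vary like the clones. All 11 libraries were fitted with a run term, which counts 3 clones with 2 libraries each and so makes p-values too small. Guide pairs AG (3 clones) and AH (2 clones) were compared in a run 1 fit with 3 groups. Repeats of a clone were compared by Pearson correlation across genes of deviations from the mean of the knockout libraries of the run.

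Before the data were examined, 31 gene lists were fixed for pathways of the tumour, reported SIX1 functions and other cell types. The 27 lists with at least 5 members after filtering were tested with camera (limma 3.58.1, voom values, preset inter-gene correlation of 0.01), and again with an estimated correlation. Named genes also followed a rule fixed at that point. It took Six1, Six4 and Hnf4a, and up to 10 genes per direction with the largest fold change. These had to pass the threshold in run 1, reach 5 CPM in the higher group, hold all 5 clones outside the range of the 2 controls, move the same way in run 2, and carry no predicted-gene name. For each list it took up to 4 members past the threshold, or else the most abundant member or none. For the guide pairs it took 5 genes per direction. The extension of this rule to the fit of both runs, and the naming of list members that passed only when adjusted over the list alone, were decided after the values were seen. Of the 37 genes named by these rules, 13 overlap an annotated gene on the other strand. Reads of such pairs cannot be told apart if strand was not used in counting, and this concerns mainly Spns2 and Sdr39u1, whose overlapping partners Mybbp1a and Khnyn had more counts.

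Run 1 libraries held 17688205 to 22180798 counts and run 2 libraries 9098266 to 11626514. The tests were checked on data simulated from the real means and library sizes, with 50 changed genes for each fold size. Changed genes were drawn only from those with a mean of at least 5 CPM, so the shares recovered do not cover less abundant genes. At a 2-fold, 4-fold, 8-fold and 16-fold change, the run 1 test recovered 6%, 64%, 90% and 98% of the changed genes among 13629, and 3.01% of its calls were false. The run 2 test recovered 0%, 58%, 78% and 86% among 13094, with 14.0% false calls. The fit of both runs recovered 38%, 90%, 92% and 94% among 13638, with 1.88% false calls. Every library was simulated independently, so simulated repeats of a clone shared no deviation. In the data, limma-voom with the cell population as a random block gave a correlation of 0.686 within a population. The shares of the fit of both runs leave this dependence out and cannot show its effect on false calls. The guide pair test recovered 8%, 76%, 92% and 98%, with 6.80% false calls.

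Alternatives were other scalings (RLE, upper quartile), no low-count filter or a mean count of at least 50, DESeq2 1.42.0, limma-voom, a test for changes beyond 1.5-fold, other sets of libraries, the cell population as a random block, run 1 thinned to the depth of run 2, and each library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.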

Results

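Transcript levels were measured by RNA-seq in 11 libraries of the mouse PDAC line HC800-A8-1, of which 3 were non-targeting controls and 8 came from 5 single-cell clones with CRISPR knockout of both Six1 and Six4. SIX1 and SIX4 are homeobox transcription factors, best known from muscle, kidney and sensory organ development. The design asked how the transcriptome of these pancreatic cancer cells differs between control and double knockout. Run 1 held controls 1 and 2 and all 5 clones at 17688205 to 22180798 counts per library, with 17884 to 19091 genes detected. Run 2 held control 3 and repeats of AH#24, AG#15 and AG#2 at 9098266 to 11626514 counts, with 17121 to 18241 genes detected.

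The transcripts of the targeted genes did not differ between control and knockout clones by the edgeR test. Six1 (ENSMUSG00000051367, chromosome 12, 73040015 to 73053887, minus strand, GRCm38) was at 18.9 ± 1.81 CPM in the controls (SD, n = 2) and 20.6 ± 6.17 CPM in the clones (SD, n = 5) of run 1. Its log2 fold change was 0.13 (SE 0.33, adjusted p = 0.953, edgeR). Six4 (ENSMUSG00000034460, chromosome 12, 73099609 to 73113456, minus strand) was at 18.8 ± 1.3 CPM in the controls and 17.9 ± 9.78 CPM in the clones, a log2 fold change of -0.07 (SE 0.46, adjusted p = 0.981). Cas9 guides make small insertions or deletions that need not lower a transcript, so counts per gene neither bear out nor contradict the knockout labels. Among the 6 tested genes of the SIX-EYA-DACH network, which holds their binding partners, none passed the threshold, and the list had an adjusted camera p of 0.658. All libraries carry the label Hnf4a-negative. HNF4A is a transcription factor of gut and liver epithelium, and its transcript was counted in every library. Hnf4a was at 32.8 ± 9.94 CPM in the run 1 controls (SD, n = 2) and 47.5 ± 33.0 CPM in the run 1 clones (SD, n = 5), which did not differ by the edgeR test (log2 fold change 0.53, SE 0.63, adjusted p = 0.885).

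Transcripts of Lox, Mrc2 and several other genes were near the detection limit in the double knockout clones. Every knockout library came from a single-cell clone and no control library did, so differences from the controls may reflect knockout or cloning. Lox, which crosslinks collagen and elastin, was at 318 and 91.0 CPM in the run 1 controls and at 0.104 CPM or less in the 5 clones (adjusted p = 0.00135). Mrc2, an endocytic collagen receptor, was at 118 and 88.7 CPM in the controls and had 0 counts in all 5 clones (adjusted p = 0.00798). Set against the mean of the run 1 controls, that is at least 3474-fold lower in these run 1 libraries by counting error alone. The bound leaves out the spread between controls and between libraries of a clone. Run 2 libraries of 3 of these clones held Mrc2 at 0.106 to 0.170 CPM, above the 0.0298 CPM floor behind the bound. In total, 18 genes were lower and 1 was higher in the knockout among 13629 tested (edgeR). The rule for named genes, which asks for at least 5 CPM in the higher group, all 5 clones outside the range of the controls, the same direction in run 2 and no predicted-gene name, was met by 15 of the lower genes and by the higher one. At an unadjusted p under 0.05, 455 genes were lower and 468 higher.

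Foxf1, a forkhead factor of mesenchyme, went from 18.8 and 18.2 CPM in the controls to 4 counts over all 5 clones together (adjusted p = 0.0150). Cxcl12, a chemokine typical of stromal cells, was at 13.4 and 12.2 CPM against 1 count in total over the clones (adjusted p = 0.00479). Grb10, an adaptor of insulin and IGF receptors, was at 42.9 and 21.4 CPM against 2 counts (adjusted p = 0.00212), and S1pr1, a receptor for sphingosine phosphate, at 6.06 and 4.56 CPM against 1 count (adjusted p = 0.00972). Stac2, an adaptor protein of calcium channels, was at 61.0 and 50.1 CPM against 3 counts (adjusted p = 0.00135). Ldhb, a lactate dehydrogenase subunit, was at 15.6 and 8.29 CPM against 3 counts (adjusted p = 0.0335). Efemp1, a fibulin of the extracellular matrix, averaged 11.4 CPM in the controls against 6 counts over the clones (adjusted p = 0.00651). The membrane protein gene Tmem119 had a log2 fold change of -7.21 (SE 0.58, adjusted p = 0.00479), from 39.0 ± 27.3 CPM (SD, n = 2) to 0.257 ± 0.135 CPM (SD, n = 5).

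The remaining genes called lower, named here after their values were seen, were Sulf2, an extracellular heparan sulfatase that fell by 4.08 on the log2 scale, Emilin1 and Col11a1 of the matrix, Rbp1, which binds retinol, the interferon-induced Oasl1, Olfml3, Mrgprf and the predicted gene Gm48898. Unc13b, which encodes a protein that primes vesicles for exocytosis, was the gene called higher. It rose from 3.95 and 4.02 CPM in the controls to between 24.7 and 36.7 CPM in the 5 clones, a log2 fold change of 3.04 (SE 0.26, adjusted p = 0.00491). Itgb4, the integrin subunit of hemidesmosomes, missed the threshold narrowly (adjusted p = 0.0501), at 17.4 ± 5.15 CPM in the controls (SD, n = 2) and 123 ± 37.8 CPM in the clones (SD, n = 5). Without control replicate 1 the edgeR test kept 1 of the 19 calls and without control replicate 2 it kept 5, in each case with 0 genes higher (241 and 82 at an unadjusted p under 0.05), without AG#15 it kept 8, and without AH#3, AG#12 or AH#24 it called 2 genes higher. Leaving out a control replicate leaves 1 control library, so only the clones give the spread there. All 19 genes kept their sign in these fits. DESeq2 called 95 genes lower and 69 higher and limma-voom 60 lower and 2 higher, each including all 19.

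**Figure D1:**
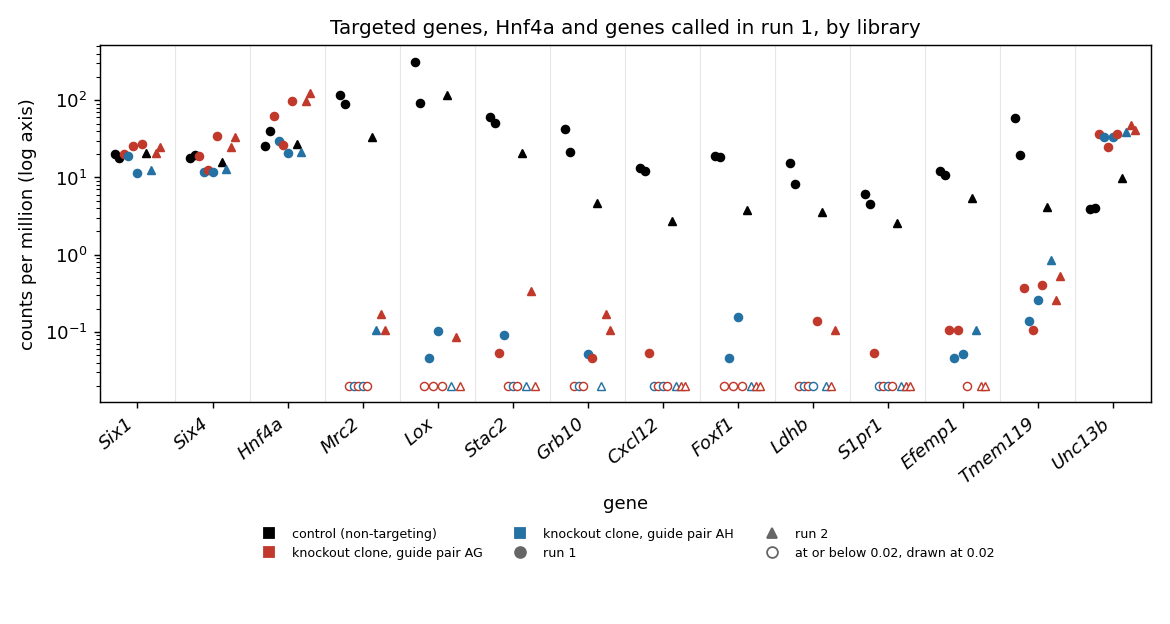
CPM (log axis) of the targeted genes, Hnf4a and the genes named for run 1, with 1 point per library; black marks controls, red AG clones and blue AH clones, circles run 1 and triangles run 2, and open symbols lie at or below 0.02 CPM. Six1 and Six4 overlap between controls and clones, while the genes from Mrc2 to Tmem119 lie below all 3 controls in all 8 knockout libraries and Unc13b lies above them.

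Extracellular matrix genes were lower as a group in the clones. Of 25 tested members, 20 had a negative fold change, the median log2 fold change was -0.65 and camera gave an adjusted p of 5.91e-08. The call did not hold with an estimated inter-gene correlation (adjusted p = 0.256 with an estimated correlation). Control replicate 1 had the highest CPM of the 3 controls for 22 of the 25 members, and for 15 of 24 EMT and 7 of 9 fibroblast members, a tally made after the values were seen. Without that library camera gave the matrix list an adjusted p of 2.23e-05. Lox was the member called over all genes, and 5 were lower when adjusted over the list alone (Lox, Loxl1, Col3a1, Fbn1 and Thbs1). Col3a1, a fibrillar collagen, was at 488 and 192 CPM in the run 1 controls and between 0 and 4.73 CPM in the 5 clones, with an adjusted p of 0.134 over all genes. The EMT and mesenchymal list was lower as well (18 of 24 members negative, adjusted p = 0.000124), but did not hold at that setting (adjusted p = 0.812 with an estimated correlation). None of its members was called over all genes, and 4 were lower adjusted over the list alone, among them the gelatinase gene Mmp2, Prrx1, a transcription factor of mesenchyme, and Acta2, smooth muscle actin. The fibroblast list was lower with 9 of its 17 members tested, 5 of them negative and 4 positive (median -2.70, adjusted p = 0.000446), and this call was lost too (adjusted p = 0.755 with an estimated correlation). Among its members, Pdgfrb was at 23.04 to 198 CPM in the 3 controls and 0.137 to 22.2 CPM in the 8 knockout libraries, while others lay on both sides of the controls. Pdgfra was at 12.8 to 28.3 CPM in the controls and 6.23 to 99.1 CPM in the knockout libraries, C3 at 7.80 to 13.1 CPM and 0.909 to 196 CPM, and Ly6c1 at most 85.6 CPM and 12.96 to 234 CPM, and none of these 4 was called. Col3a1 and Mgp were lower adjusted over that list alone, while the fibroblast transcripts Lum, Thy1 and Pdpn had 0 CPM in all 11 libraries and Dcn at most 0.196 CPM.

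Interferon-stimulated genes were also lower as a group (21 of 28 members negative, median log2 fold change -0.81, camera adjusted p = 2.11e-06). This call did not hold at that setting (adjusted p = 0.812 with an estimated correlation). Oasl1 was the member called over all genes and the member lower when adjusted over the list alone, at 41.6 and 26.9 CPM in the controls and 1.54 to 5.22 CPM in the clones of run 1. Oasl1 was higher still in control replicate 3 (65.2 CPM). The chemokine and inflammatory cytokine list was lower by camera (adjusted p = 0.000264) with 10 of 17 members negative, and the call was lost in the same way (adjusted p = 0.256 with an estimated correlation). Cxcl12 was the member called, both over all genes and adjusted over the list alone. Genes of the unfolded protein and amino acid stress response were higher as a group (17 of 22 members positive, median 0.32, adjusted p = 0.0261), with no member called over all genes or over the list alone. That call was lost with an estimated correlation (adjusted p = 0.812), and without AG#15 (adjusted p = 0.101) or AG#2 (adjusted p = 0.0966). Without control replicate 2 the direction turned, with an adjusted p of 0.997. Hspa5, the chaperone BiP and the most abundant member, was at 1234 and 969 CPM in the run 1 controls and at 937 to 1185 CPM in the clones.

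None of the other 21 tested lists passed. Epithelial genes had 13 of 14 tested members positive and a median log2 fold change of 1.11 (adjusted p = 0.208). Over that list alone the keratin gene Krt8 and the tight junction gene Tjp3 were higher and the claudin gene Cldn6 was lower. Hypoxia response genes (adjusted p = 0.0922), immediate early genes (0.0945), YAP-TEAD targets (0.181), DNA replication genes (0.236), glycolysis genes (0.321), Notch pathway genes (0.380) and reported SIX1 targets (0.392) followed by camera p. Basal and squamous genes and mitotic genes had an adjusted p of 0.468, TGF-beta pathway genes 0.610, the skeletal muscle programme 0.806, cholesterol synthesis genes 0.815 and RAS-MAPK output genes 0.870. Stem and progenitor genes, classical and gastrointestinal genes, neural genes, p53 targets, WNT targets and MHC class I antigen presentation genes were all at 0.993. Adjusted over the list alone, Itgb4 of the basal list and Aldoc of the glycolysis list were higher and Apcdd1 of the WNT list was lower. The median and the camera direction differed in sign for the TGF-beta, cholesterol, RAS-MAPK, classical and WNT lists. Blood, endothelial, acinar and endocrine markers had 1 to 3 members above the filter and were not tested as lists.

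In run 2, with another control library and new libraries of 3 clones, the genes called in run 1 moved the same way. All 19 had the same sign by mean CPM, as did all 16 that passed the run 2 filter. The 3 clones were also in run 1, so no new clone was added. Each of the 16 had a smaller fitted fold change in run 2, with log2 fold changes of -2.91 against -7.21 for Tmem119 and -1.18 against -5.07 for Rbp1. The 16 were selected by their run 1 test, which by itself favours larger changes there. Cxcl12, S1pr1 and Foxf1 were at 0 CPM in the 3 knockout libraries of run 2, so their fitted folds there depend on prior count and depth. Rbp1 was at 2.73 CPM in control replicate 3 and up to 2.64 CPM in the knockout libraries. For Gm48898 the sign rests on 0.0941 CPM in control replicate 3 against 0 CPM. Mrc2 was at 33.0 CPM in control replicate 3 and at most 0.170 CPM in the 3 knockout libraries, and Lox at 116 CPM against 0.0849 CPM or less. Unc13b was at 9.78 CPM in control replicate 3 and between 38.9 and 48.4 CPM in the clones. Across 12882 genes the log2 fold changes of the runs correlated at Pearson r = 0.509, which is across genes and not across independent replicates, and 54.3% of all genes had the same sign. With 1 control library, edgeR called 0 of 13094 genes (245 lower and 249 higher at an unadjusted p under 0.05) and limma-voom 0 (330 lower and 182 higher at an unadjusted p under 0.05), while DESeq2 called 28 lower and 39 higher. Set against control replicate 3 alone, the matrix, EMT and interferon-stimulated lists had a camera adjusted p of 0.0121, 0.0332 and 1.54e-40 in the lower direction, and adjusted p = 0.482, 0.582 and 0.482 with an estimated correlation. With 1 control library these values describe how that library differed from 3 clones and are no repeat of the list results of run 1, and the median of the matrix list was -0.04. The chemokine and fibroblast lists did not pass (adjusted p = 0.267 for each) and had positive medians of 0.42 and 0.39. The unfolded protein list had the opposite direction (adjusted p = 0.0649).

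The fit of all 11 libraries with a run term called 44 genes lower and 19 higher among 13638, including 16 of the 19 run 1 calls with the same sign. By the naming rule, extended to this fit after its values were seen, the genes with the largest falls were Lox, Mrc2, Vgll3, Klrk1, Tspan11, Stac2, Cxcl12, Grb10, Rem1 and Foxf1. A limma-voom fit took the population as a random block, which allows for repeats of a clone and also groups the 3 controls as 1 population. With that block, Lox, Grb10, Rem1 and Tspan11 missed the threshold (adjusted p = 0.0744, 0.102, 0.111 and 0.146) and the other 6 passed it, at adjusted p = 0.00679 to 0.0159. Vgll3, a cofactor of TEAD transcription factors, was at 14.3 ± 5.91 CPM in the controls (SD, n = 3) and had 0 counts in the 8 knockout libraries, at least 517-fold lower in run 1 (adjusted p = 0.0212 in the fit of both runs and 0.0571 in run 1). Klrk1, which encodes an activating receptor of lymphocytes, was at 8.27 ± 3.60 CPM in the controls and had 0 counts in the knockout libraries, at least 329-fold lower in run 1 (adjusted p = 0.0221 and 0.0571). Tspan11, a tetraspanin gene, and Rem1, which encodes a small GTPase, had 0 counts in the 5 clones of run 1, at least 388-fold and 356-fold lower there. Their adjusted p was 0.0265 and 4.27e-04 in the fit of both runs and 0.0561 and 0.0508 in run 1, so none of these 4 genes was called in run 1. As for Mrc2, the bounds on the folds of these 4 genes cover counting error only. Vgll3, Klrk1 and Tspan11 also missed the threshold in the fit of both runs without any 1 of the 3 controls (adjusted p = 0.0531 to 0.285), and Tspan11 with no run term (adjusted p = 0.0669).

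Genes called higher in that fit were led by Cryl1, Itgb4, Unc13b, Chrd, Dmrta2, Nradd, P3h4, Rom1, Dmpk and Ablim3. Itgb4 was at 14.4 ± 6.37 CPM in the controls (SD, n = 3) and 127 ± 32.4 CPM in the knockout libraries (SD, n = 8), a log2 fold change of 3.17 (SE 0.35, adjusted p = 0.00151). P3h4, an endoplasmic reticulum protein of collagen modification, was at 11.9 ± 4.90 and 41.2 ± 7.97 CPM, a log2 fold change of 1.83 (SE 0.30, adjusted p = 0.0221). Chrd, the BMP antagonist chordin, had a log2 fold change of 2.57 (SE 0.48, adjusted p = 0.0482). With the population as a random block, limma-voom called 21 genes lower and 0 higher (78 higher at an unadjusted p under 0.05), kept 15 of the 63 calls and none of the genes named as higher, and gave Itgb4 and Unc13b an adjusted p of 0.138 and 0.0744. Without the block it called 86 lower and 19 higher. The log2 fold changes of Itgb4 and Unc13b were 2.86 and 2.79 with the block and 3.13 and 2.74 without it. Without any 1 of the controls, the edgeR calls of the named higher genes other than Itgb4 and Unc13b were lost (adjusted p = 0.0620 to 0.340). Leaving out control replicate 1, 2 or 3 gave 21, 24 and 30 genes lower and 2, 2 and 3 higher, and leaving out the run 1 or run 2 library gave 8 and 6 higher for AG#15, 9 and 10 for AH#24, and 5 and 9 for AG#2.

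Clones made with different Six4 guides differed in several genes, some of them on in only 1 of the pairs. Car8, a carbonic anhydrase-related protein, was at 212, 121 and 201 CPM in the AG clones of run 1 and had 0 counts in both AH clones (adjusted p = 0.0201). Ereg, an EGF receptor ligand, was at 10.4 to 32.1 CPM in the AG clones and at most 0.0458 CPM in the AH clones (adjusted p = 0.0259). In the other direction, the lymphatic growth factor gene Vegfc was at 0 counts in the AG clones and at 4.17 and 9.73 CPM in the AH clones (adjusted p = 0.0487). Wnt7b, a WNT ligand, was at 0.373 to 0.636 CPM in AG and 11.8 and 18.7 CPM in AH (log2 AG minus AH -4.97, SE 0.45, adjusted p = 0.0201). Cyp26b1, which degrades retinoic acid, was at 8.39 CPM on average in AG and 57.9 CPM in AH (log2 -2.79, SE 0.22, adjusted p = 0.0201). In all, 16 genes were higher and 9 lower in AG by edgeR (1047 and 684 at an unadjusted p under 0.05), among 13629 tested. In the 3 controls Car8 was at 2.92 to 24.5 CPM, Ereg at 19.6 to 33.4 CPM, Vegfc at 2.35 to 8.45 CPM and Wnt7b at 1.41 to 6.28 CPM. DESeq2 called 452 higher and 224 lower. Without AG#12 there were 123 higher and 118 lower, without AG#15 or AH#3 there were 0 by edgeR (788 and 910 higher at an unadjusted p under 0.05), without AH#24 1 higher and without AG#2 3 higher.

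**Figure D2:**
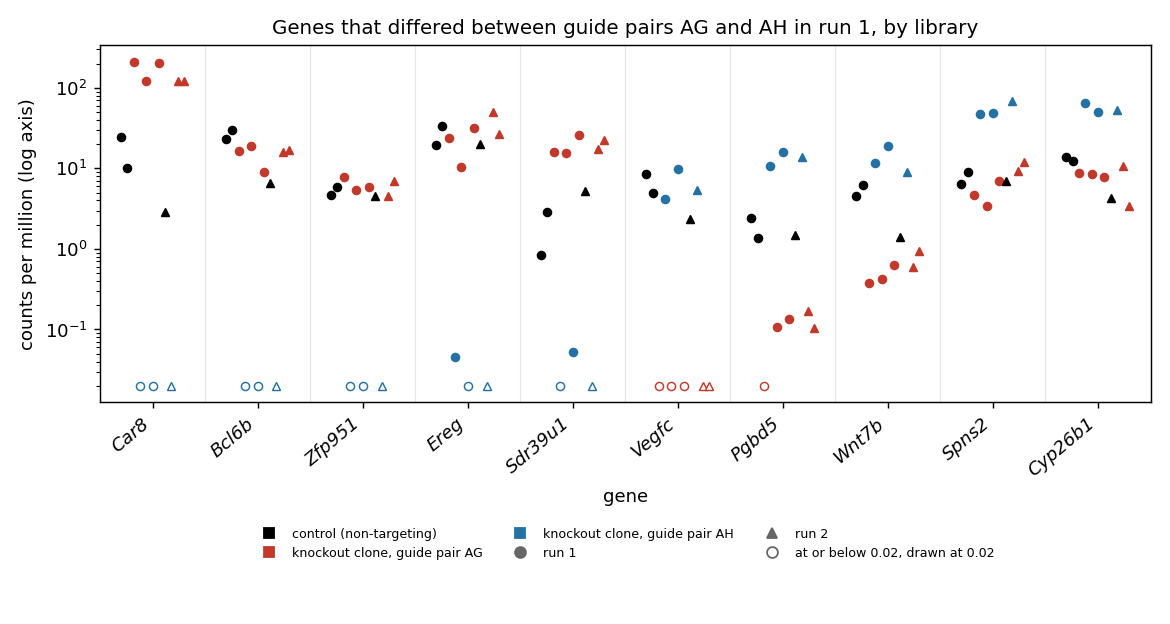
CPM (log axis) of the 10 genes named for the comparison of guide pairs, with 1 point per library; black marks controls, red AG clones and blue AH clones, circles run 1 and triangles run 2, and open symbols lie at or below 0.02 CPM. Car8 lies between 121 and 212 CPM in the run 1 AG clones and at the bottom of the plot in all AH libraries.

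Libraries of one clone stayed alike between runs, and differences between clones were the largest component of the data. The same clone in different runs correlated at r = 0.983 to 0.988 in log2 CPM across genes, different clones at 0.912 to 0.966 and control libraries with each other at 0.964 to 0.982. The run 2 libraries deviated from the knockout mean together with the run 1 library of the clone in their title, at r = 0.810 for AH#24, 0.772 for AG#15 and 0.687 for AG#2. Each of these was the highest among the 5 clones, and the clones that their descriptions name (AG#15, AH#3 and AG#12 in that order) gave -0.655, -0.245 and 0.144. Principal component 1 held 32.9% of the variance and parted AG#15 and AG#2 from AH#3 and AH#24, with the controls and AG#12 between them. Principal component 2 held 18.9% and parted the 3 controls from all knockout libraries.

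**Figure D3:**
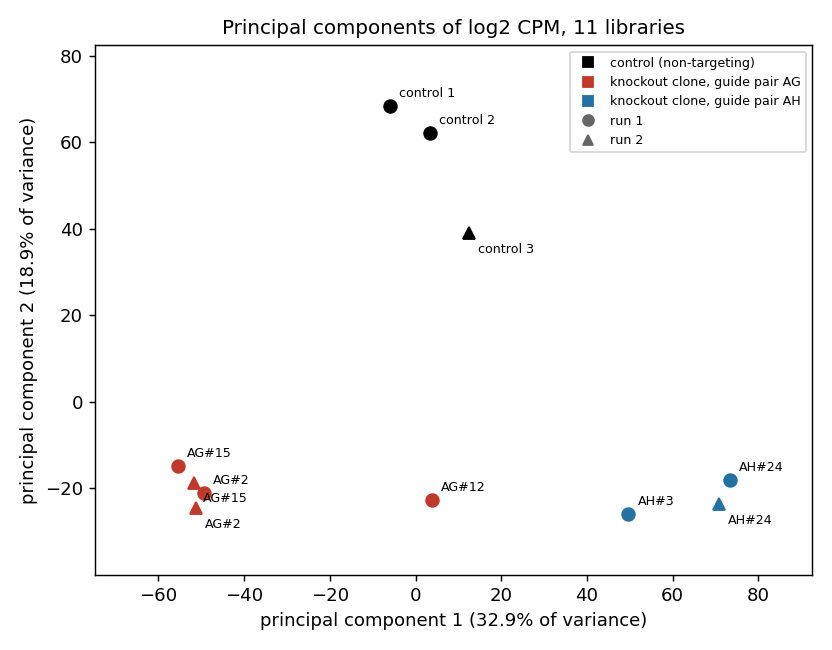
Principal components of log2 CPM over the 11 libraries, with 1 point per library; black marks controls, red AG clones and blue AH clones, circles run 1 and triangles run 2. Component 1 (32.9% of the variance) separates AG#15 and AG#2 from the AH clones, and component 2 (18.9%) separates controls from clones.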

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

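In this part only the chromosome medians against the run 1 controls were chosen after the results were seen. The 10 genes below stood out because their levels differed between clones of the guide pairs AG and AH by the edgeR test of that difference. The log2 difference AG minus AH was 14.79 for Car8, 11.21 for Bcl6b, 9.97 for Zfp951, 9.51 for Ereg and 9.29 for Sdr39u1, and on the other side -10.11 for Vegfc, -7.23 for Pgbd5, -4.97 for Wnt7b, -3.26 for Spns2 and -2.79 for Cyp26b1. Car8, Bcl6b and Zfp951 had 0 counts in the AH clones and Vegfc in the AG clones of run 1, so their fitted differences depend on the prior count and are no bounds. Each of the 10 had the same order in the run 2 libraries. Those are repeat libraries of clones also used to pick these genes, so they add no clone to the comparison of guide pairs. Spns2 overlaps Mybbp1a (602 CPM on average) and Sdr39u1 overlaps Khnyn (31.8 CPM) on the other strand, and the strand setting of the counting is not given in the sources used here. The groups hold 3 and 2 clones, and each clone grew from 1 cell, so guide pair and clone cannot be separated for single genes.

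A candidate explanation for part of the differences between clones is gain or loss of whole chromosomes. Of 60 pairs of a chromosome and a repeated clone, 10 had a median shift beyond 0.3 on the log2 scale in both libraries of the clone, against 0 in each of 1000 draws with chromosome labels reassigned at random. Medians over many randomly labelled genes vary little. The draws therefore show only that genes of a chromosome shifted together, and cannot tell copy number from other shared shifts. The 10 pairs are not separate events, since a shift in any clone moves the values of the clones set against it. Chromosome X passed in each repeated clone. Against the other repeated clones, the shifts included chromosome X at 1.04 and 1.01 and chromosome 12, which carries Six1 and Six4, at -0.36 and -0.42 in AH#24, and chromosome 9 at -0.45 and -0.48 in AG#15. Against the run 1 controls the same medians were 0.52 and 0.59, -0.08 and -0.09, and -0.16 and -0.19, so chromosomes 12 and 9 did not pass 0.3 there. Chromosome 16 in AG#2 did, at 0.60 and 0.60, with control replicate 3 at 0.18. Chromosomes 6, 14 and 18 in AH#24 and 18 in AG#2, also among the 10 pairs, did not. Outside the 10 pairs, chromosome 8 in AG#15 (-0.39 and -0.40), 14 in AG#15 and AG#2, and 19 in AH#24 passed 0.3 against the controls. Chromosome X passed 0.3 in AH#24, but also in control replicate 3, at 0.39, and that library came from no single-cell clone. Copy number was not measured. Effects of the Six4 guides themselves stay open.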

How the results depend on the processing

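Of the alternatives below, 3 controls against the 5 run 1 clones, run 1 thinned to the depth of run 2, limma-voom on both runs without a block, the lists without genes lost in every clone, and the naming rule on the fit of both runs were chosen after seeing the data. Every gene called in run 1 kept its sign under each alternative of the run 1 test that tested it. All 19 were tested in most, 15 with a mean count of at least 50, 16 in run 2 alone, 17 with all 11 libraries and with 3 controls against 5 clones, and 18 with counts summed per clone. Six1 and Six4, called in none, had log2 fold changes on both sides of 0, from -0.11 (run 2) to 0.29 for Six1 and from -0.44 (without AG#2) to 0.56 (run 2) for Six4. For run 1, genes higher numbered 1, and 2 with RLE, with upper quartile scaling, with a mean count of at least 50, with limma-voom, with 3 controls against 5 clones and with thinned counts, 3 with no low-count filter and with counts summed per clone over the runs, 69 with DESeq2, 19 and 18 with all 11 libraries with and without a run term, and 0 with the population as a random block (78 at an unadjusted p under 0.05) and in run 2 alone (249). Genes lower numbered 18, and 46 with no low-count filter, 95 with DESeq2, 60 with limma-voom, 44 and 51 with all 11 libraries with and without a run term, 28 with counts summed per clone, 7 with the 3 repeated clones and 0 in run 2 alone (245). Leaving out each replicate gave 0 to 2 higher and 1 to 23 lower.

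Lists higher numbered 1, and 0 with the estimated correlation and 4 in run 2 alone. Lists lower numbered 5, and 0 with the estimated correlation and 7 in run 2 alone. Those 7 include the hypoxia, glycolysis and cholesterol lists (adjusted p = 4.99e-04, 1.09e-04 and 0.00800), which camera placed in the higher direction in run 1, and no list passed in run 2 with the estimated correlation. Leaving out each replicate gave 0 to 4 lists higher and 5 to 8 lower. Leaving out the genes lost in every clone kept 1 higher and 5 lower.

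For AG against AH, 16 genes higher and 9 lower became 273 and 170 with no low-count filter, 452 and 224 with DESeq2, and 316 and 222 with all 8 knockout libraries and a run term. Leaving out each replicate gave 0 to 123 higher and 0 to 118 lower. For both runs, 19 higher and 44 lower became 19 and 86 with limma-voom without a block and 0 and 21 with limma-voom and the population as a random block, and leaving out each replicate gave 2 to 18 higher and 21 to 51 lower. The limma-voom fits of both runs differ in the block alone, which groups the control libraries as well as the repeats of a clone. The cause of the other moves was not tested. Run 2 held 9098266 to 11626514 counts per library. Run 1 thinned at random to 9098266 counts per library gave 20 genes lower and 2 higher and kept 15 of the 19 calls, losing Lox (adjusted p = 0.0791) and S1pr1 (adjusted p = 0.132) among others, so 2 controls and 5 clones gave calls at that depth. The 0 calls of run 2 came with a single control, and their cause was not tested. Changes of 2-fold were mostly below what any fit recovered in simulated data. No paired analysis was possible because the knockout labels number only the repeat library of a clone, and no number ties a control to a knockout library.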

Other observations

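The SD over genes with at least 30 counts, the tally of interferon-stimulated members, the count of genes by the mirrored rule and the chromosome X values below were chosen after the results were seen.

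Interferon-stimulated transcripts were highest in control replicate 3 among the control libraries. All 28 tested members of the list had a higher CPM there than in control replicates 1 and 2. Ifit1 was at 122 CPM against 48.7 and 23.4 CPM in the other controls, and Cxcl10 at 125 CPM against 62.2 and 25.5 CPM. CPM was scaled within each run, and the difference between control libraries was not tested.

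A set of 30 genes was at 2 CPM or more on average in the run 1 controls and under 0.05 of that mean in all 8 knockout libraries. It holds Col3a1, Mmp2, Lox, Mrc2, Foxf1, its neighbouring noncoding transcript Fendrr, the protocadherin genes Pcdh18 and Pcdh19, Vgll3 and Aspn. By the mirrored rule, 7 genes were at 2 CPM or more on average in the run 1 clones and under 0.05 of that mean in all 3 controls, and each of them was under 2 CPM in at least 1 of the 5 clones. Single clones also lost other genes. Counted clone by clone among 11207 genes, losses ranged from 122 genes in AG#15 to 256 in AH#3. Of these genes, 174, 93, 69 and 39 were lost in 1, 2, 3 and 4 clones, and 33 in all 5. Within the controls the set of 30 varied too, as 29 of the 30 genes were lower in control replicate 3 than in control replicate 1, with a median log2 ratio of -2.41, against medians of -0.48 to 0.43 in 10000 sets of other genes of like abundance. In control replicate 2, 27 of the 30 were lower than in control replicate 1 (median -0.80). The set was picked for its level in the run 1 controls and its loss in the clones, and the matched sets were not. Part of the fall in control replicate 3 may come from that choice.

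These losses may come from the double knockout, or from single-cell cloning out of a mixed population in which some cells carried these transcripts, and with 0 single-cell clones of control cells among the libraries, knockout and cloning cannot be told apart here. If the transcripts came from 1 subpopulation, their ratios between controls would share a value and spread less than those of other genes, which was not seen. The SD of the log2 ratio of control replicate 3 to 1 was 1.34 over the 30 genes, against 0.490 to 1.257 in sets matched on run 1 abundance and 1.20 to 1.94 in sets matched on control replicate 3, and 0.921 over the 16 genes with at least 30 counts in every control, against 0.298 to 0.891 and 0.392 to 1.16. Both values lie above the first range and within the second, and the bound set beforehand did not name the library for matching, so 1 subpopulation with a shared ratio stays open.

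Chance was weighed by regrouping the libraries. Of the 21 splits of the 7 run 1 libraries into 2 and 5, only 1, the real one, gave 19 or more calls, and the highest other gave 9 (AH#3 and AH#24 set apart). Of 84 splits of all 11 libraries that kept 2 run 1 and 1 run 2 library apart, 2 gave at least the 63 calls of the real split. The other, with 317 calls, set apart AH#3 and both AH#24 libraries, which points to the structure among clones described above. A share of 1 in 21 is the smallest those splits allow. Controls correlated with each other at r = 0.964 to 0.982 across genes and different clones at 0.912 to 0.966, and most of the 84 splits part libraries of one clone, so the libraries are not interchangeable and these shares do not by themselves exclude chance.

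Median log2 levels of 307 chromosome X genes against the mean of the run 1 controls were -0.48 and -0.52 in AG#15, -0.47 and -0.41 in AG#2, 0.48 in AH#3, 0.56 in AG#12, 0.52 and 0.59 in AH#24, and 0.39 in control replicate 3.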
